A study of Rattus norvegicus with 24 samples.

How the data were processed

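RNA sequencing libraries were made from the livers of 24 female Sprague-Dawley rats, an outbred stock. The rats received sesame oil vehicle or TCDD by oral gavage every 4 days, and livers were taken on day 28. TCDD is a chlorinated dioxin and a ligand of the aryl hydrocarbon receptor. The 7 doses were 10, 3, 1, 0.3, 0.1, 0.03 and 0.01 µg/kg. Each of the 8 groups held 3 libraries, which the series describes as biological replicates. Groups and replicate numbers were taken from the dose and replicate labels.

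The deposited values were whole-number counts per Ensembl gene ID, not normalised, in 1 table per library with 26404 gene IDs. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were prepared with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the tools used upstream were FastQC 0.11.2, cutadapt 1.4.1, TopHat 1.4.1, SAMtools 0.1.2, HTSeq 0.6.1 and DESeq. The notes gave neither the order of the tools nor their settings. The genome build, the annotation release and the strand setting of the counting were not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, are therefore uncertain at the level of a single gene ID. Each table ended in 5 HTSeq summary rows that name no gene, and these were kept out of library sizes and tests. They held 35.8% to 47.5% of a table's total. Most of this was alignments that were not unique (21.0% to 35.0%) and alignments outside annotated genes (12.0% to 17.7%). Alignments assigned to more than 1 gene were at most 0.00689%.

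Neither the count tables nor the RefSeq gene table used here paired these Ensembl IDs with gene names: 0 of the 26404 IDs matched, since 0 of the 47357 rows of the gene table held an Ensembl ID. The gene lists fixed before the data were examined, the exposure checks by symbol and the symbol condition of the rule for named genes could not be applied. Genes are therefore reported as counts, with 2 IDs that rose and 2 that fell. The rule took the largest called changes at 10 µg/kg among IDs with a mean of at least 5 CPM in the higher group and no overlap between the 3 treated and the 3 vehicle libraries. Those are the largest rise and both of the falls. The other ID that rose was the gene called at 0.01 µg/kg, which the rule names because 5 or fewer were called there. The full rule would also name the other gene called at 0.03 µg/kg. It would further name more IDs at 10 µg/kg, at the doses between, for 10 against 3 µg/kg and for the dose trend. All of these were left out because at most 2 IDs were named each way.

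Counts assigned to genes ranged from 11816273 to 15804887 per library. A count of 3 in a vehicle library corresponds to about 0.242 CPM, which was taken as the floor for detection. Replicate libraries of a group differed by more than sampling noise in every pair, with chi-square values of 13.9 to 58.4 per degree of freedom, so no library was treated as a repeat of another.

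Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 8 groups, which left 12496 of the 18198 IDs with at least 1 count. Library sizes were scaled by TMM, with factors from 0.898 to 1.11. A quasi-likelihood model with a mean for each group (glmQLFit, 16 residual degrees of freedom) was fitted to all 24 libraries, so that the groups shared an estimate of the spread. The biological coefficient of variation from the common dispersion was 22.3%. Each dose was tested against vehicle and 10 against 3 µg/kg with glmQLFTest. The hypothesis of no difference among the 8 groups was tested with the F test, and a trend was fitted on the rank of the dose. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05 with no minimum fold change. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values used TMM-scaled library sizes and are given as mean ± SD (n = 3). Principal components were computed on log2 CPM with a prior count of 2.

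The pipeline was tested on simulated counts for the 12496 genes with 200 changed genes, 100 of them by 2-fold and 100 by 4-fold. For 10 µg/kg against vehicle, edgeR called 54 of the 2-fold and 85 of the 4-fold changes, and 12 of its 151 calls were false. For 10 against 3 µg/kg it called 57 and 82, for any dose 45 and 84, and for the trend 64 and 95, where the fold is that reached at the highest dose. DESeq2 called 59 and 88 for 10 µg/kg against vehicle, and 31 of its 178 calls were false. No called change had the wrong sign in the comparisons with a direction.

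The alternatives, chosen before the data were examined, were RLE scaling, DESeq2 1.42.0, no low-count filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, a fit of only the 2 groups compared, log10 of dose + 0.01 for the trend, and leaving out each library in turn (those of the 2 groups compared, or all 24 for any dose and the trend). Comparisons against vehicle shared the same 3 vehicle libraries. Overlaps and covariances of their fold changes were therefore set beside 20 simulations of unchanged groups and beside the overlap that independent lists would give. The simulations drew each gene independently around 1 mean over all 24 libraries, so genes changed by dose did not keep their vehicle level. The 3 vehicle libraries could not be split into sets of at least 2 libraries each. Permutation tests and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.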

Results

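Hepatic gene expression was measured by RNA sequencing in female rats given vehicle or 1 of 7 doses of TCDD for 28 days, with 3 libraries per group. The series title places the study in the field of hepatic polyunsaturated fatty acid metabolism and eicosanoid synthesis. The comparisons ask which genes change at each dose and from which dose on. Gene counts per library ranged from 11816273 to 15804887, with a mean of 12809182 ± 851540 (SD, n = 3) in vehicle and 14796144 ± 1027284 (SD, n = 3) at 10 µg/kg. IDs are given without gene names, since the sources used here did not pair them.

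The libraries were ordered by dose along the first principal component of log2 CPM, which held 31.6% of the variance. The group mean was -28.6 ± 6.75 (SD, n = 3) in vehicle, -26.8 ± 4.12 at 0.01 µg/kg, -24.2 ± 2.91 at 0.03 µg/kg and -16.6 ± 4.53 at 0.1 µg/kg. It was -6.97 ± 1.58 at 0.3 µg/kg, 9.78 ± 10.6 at 1 µg/kg, 27.1 ± 1.52 at 3 µg/kg and 66.3 ± 6.23 at 10 µg/kg. The ranges of vehicle (-35.9 to -22.5) and of the lowest 2 doses overlapped. From 0.1 µg/kg upward, the libraries of each dose lay beyond every library of vehicle and the lower doses. The ranges were -21.2 to -12.1 at 0.1 µg/kg, -8.79 to -5.89 at 0.3 µg/kg and -2.39 to 17.4 at 1 µg/kg. They were 26.1 to 28.8 at 3 µg/kg and 59.8 to 72.2 at 10 µg/kg.

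**Figure D1:**
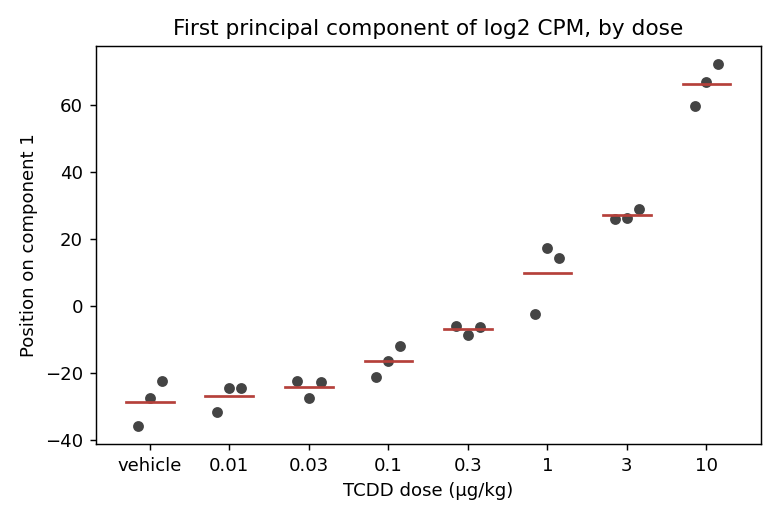
Position of each of the 24 libraries on the first principal component of log2 CPM (vertical axis, no unit) by TCDD dose in µg/kg (horizontal axis, equally spaced groups). Points are libraries and lines are group means, which run from -28.6 in vehicle to 66.3 at 10 µg/kg.

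At 10 µg/kg, 1837 genes rose and 1693 fell against vehicle, which together were 28.2% of the 12496 genes tested. The median log2 fold change was 1.14 among the genes that rose and -0.76 among those that fell. A change of at least 2-fold was fitted for 1075 rises and 550 falls, and of at least 8-fold for 157 rises and 75 falls. The genes that rose took 5.17% ± 0.360 of gene counts in vehicle and 16.1% ± 0.156 at 10 µg/kg (SD, n = 3). The genes that fell took 37.2% ± 1.14 in vehicle and 22.9% ± 0.569 at 10 µg/kg (SD, n = 3). Of the rises, 381 (20.7%) lay below 1 CPM in vehicle, and 11 of these had no count in any vehicle library, so that their fitted fold changes are no measure of size. Of the falls, 7 lay below 1 CPM in vehicle. For 2 of the falls no 10 µg/kg library held a count, so their fitted fold changes are likewise no measure of size.

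ENSRNOG00000002331 showed the largest rise among the IDs eligible to be named, from 0.344 ± 0.186 CPM in vehicle to 1654 ± 488 CPM at 10 µg/kg (SD, n = 3; log2 fold change 12.18, SE 0.938; edgeR adjusted p = 1.31e-08). Its vehicle level rested on 7, 4 and 2 counts. ENSRNOG00000019500 rose from 14.0 ± 4.39 to 9937 ± 734 CPM (log2 fold change 9.47, SE 0.616; edgeR adjusted p = 1.06e-09). ENSRNOG00000010079 showed the largest fall by the same rule, from 105 ± 56.2 to 0.523 ± 0.351 CPM (log2 fold change -7.60, SE 0.778, edgeR adjusted p = 6.63e-07). Its level at 10 µg/kg rested on 5, 16 and 5 counts. ENSRNOG00000029844 fell from 151 ± 137 to 1.03 ± 0.864 CPM (log2 fold change -7.16, SE 1.87, edgeR adjusted p = 0.00689), with 651, 1180 and 3622 counts in the vehicle libraries. Replicate 2 at 0.01, 0.03 and 0.1 µg/kg held 7, 5 and 7 counts, and replicate 3 at 0.1 µg/kg 12, against 15, 33 and 3 at 10 µg/kg. The other libraries of these 3 lower doses held 391 to 1530. Low counts of this ID were thus not confined to the highest dose. No omission of a single vehicle or 10 µg/kg library and no other setting tried ended the calls of the named IDs at 10 µg/kg. Nor did any move the count of 3530 genes at that dose by more than 1.5 times. Single libraries moved the size of both falls by more than 1.5 times: the log2 fold change of ENSRNOG00000029844 was -6.11 without vehicle replicate 3 and -8.0 without 10 µg/kg replicate 2, and that of ENSRNOG00000010079 was -8.32 without 10 µg/kg replicate 2.

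Alignments that were not unique, which enter no gene count, made up 24.1% ± 0.797 of a table's total in vehicle and 32.0% ± 2.85 at 10 µg/kg (SD, n = 3). With 3 libraries per group an exact permutation test cannot go below a p of 0.10, which was its value here (two-sided).

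**Figure D2:**
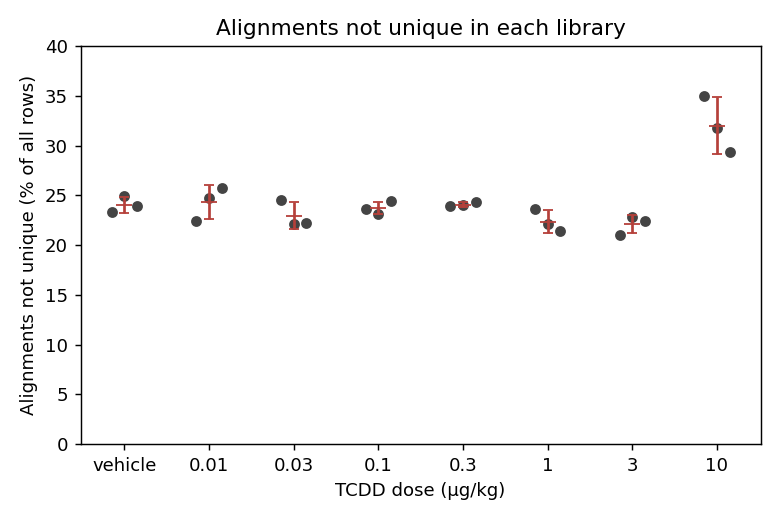
Share of each library's alignments that were not unique (vertical axis, % of all rows of its count table) by TCDD dose in µg/kg (horizontal axis, equally spaced groups). Points are libraries, and lines with bars are the group mean and SD (n = 3). The 3 libraries at 10 µg/kg lie between 29.3% and 35.0%, all above the vehicle libraries.

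**Figure D3:**
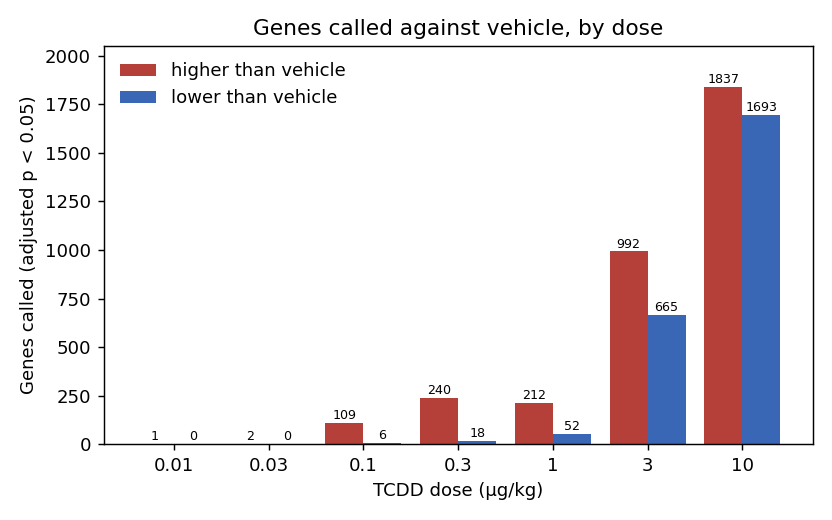
Number of genes called against vehicle (vertical axis, edgeR adjusted p below 0.05) at each TCDD dose in µg/kg (horizontal axis), with genes higher than vehicle in red and lower in blue. Rises went from 1 at 0.01 µg/kg to 1837 at 10 µg/kg, and falls from 0 to 1693.

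At 3 µg/kg, 992 genes rose and 665 fell against vehicle, with median log2 fold changes of 1.02 and -0.84. The genes that rose took 4.23% ± 0.260 of gene counts in vehicle and 12.3% ± 0.392 at this dose (SD, n = 3). ENSRNOG00000019500 had its highest mean at 3 µg/kg, 12310 ± 472 CPM (log2 fold change 9.78, SE 0.623; edgeR adjusted p = 1.44e-09). ENSRNOG00000002331 rose to 245 ± 118 CPM (log2 fold change 9.42, SE 0.879; edgeR adjusted p = 6.34e-07) and ENSRNOG00000010079 fell to 2.44 ± 1.09 CPM (log2 fold change -5.45, SE 0.671; edgeR adjusted p = 2.48e-05). ENSRNOG00000029844, at 5.74 ± 1.29 CPM, missed the threshold (log2 fold change -4.71, SE 1.60; edgeR adjusted p = 0.0562). The count of 1657 genes fell to 812 without vehicle replicate 2, to 935 without 3 µg/kg replicate 3, and to 757 in a fit of the 2 groups alone.

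At 1 µg/kg, 212 genes rose and 52 fell, with median log2 fold changes of 1.11 and -0.68. The genes that rose took 0.958% ± 0.0494 of gene counts in vehicle and 5.40% ± 0.172 at this dose (SD, n = 3). ENSRNOG00000019500 stood at 9957 ± 795 CPM (log2 fold change 9.47, SE 0.616; edgeR adjusted p = 4.23e-09). This was the lowest dose at which ENSRNOG00000002331 was called (20.0 ± 12.2 CPM; log2 fold change 5.81, SE 0.841; edgeR adjusted p = 0.000549) and ENSRNOG00000010079 was called (20.4 ± 14.0 CPM; log2 fold change -2.37, SE 0.556; edgeR adjusted p = 0.0295). The count of 264 depended on single libraries, with 110 and 66 genes without vehicle replicates 1 and 2, and 543, 68 and 100 without 1 µg/kg replicates 1, 2 and 3. DESeq2 called 625 genes and a fit of the 2 groups alone 54.

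At 0.3 µg/kg, 240 genes rose and 18 fell, and 122 of the rises were of at least 2-fold. The genes that rose took 0.658% ± 0.0633 of gene counts in vehicle and 2.76% ± 0.398 at this dose (SD, n = 3). ENSRNOG00000019500 stood at 4672 ± 1508 CPM (log2 fold change 8.38, SE 0.590; edgeR adjusted p = 2.82e-08). ENSRNOG00000010079 was at 27.1 ± 5.30 CPM and missed the threshold (log2 fold change -1.95, SE 0.547; edgeR adjusted p = 0.0657). The count of 258 was 24 and 15 without vehicle replicates 1 and 2, and 28, 33 and 465 without 0.3 µg/kg replicates 1, 2 and 3. DESeq2 called 524 genes and a fit of the 2 groups alone 7.

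At 0.1 µg/kg, 109 genes rose and 6 fell, and 69 of the rises were of at least 2-fold. The genes that rose took 0.293% ± 0.0475 of gene counts in vehicle and 1.48% ± 0.061 at this dose (SD, n = 3). ENSRNOG00000019500 stood at 3128 ± 482 CPM (log2 fold change 7.80, SE 0.576; edgeR adjusted p = 1.37e-07), while ENSRNOG00000002331 was at 0.232 ± 0.130 CPM, below the detection floor. The count of 115 was 44 and 9 without vehicle replicates 1 and 2, and 30, 28 and 37 without 0.1 µg/kg replicates 1, 2 and 3. DESeq2 called 313 genes, the fit with the replicate number as a block 183, and a fit of the 2 groups alone 42.

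At 0.01 µg/kg, ENSRNOG00000019500 was the 1 gene called, at 324 ± 229 CPM against 14.0 ± 4.39 CPM in vehicle (SD, n = 3; log2 fold change 4.53, SE 0.498; edgeR adjusted p = 0.000155). Its 3 libraries at this dose held 376, 522 and 72.5 CPM, each above the highest vehicle library at 19.1 CPM. At 0.03 µg/kg it reached 1067 ± 424 CPM (log2 fold change 6.25, SE 0.538; edgeR adjusted p = 2.27e-06), and 1 other gene rose. An unadjusted p below 0.05 was found for 1036 genes at 0.01 µg/kg and 932 at 0.03 µg/kg, where chance alone would give 625 of the 12496 tested. Without vehicle replicate 2 these counts were 547 and 553, below the number expected by chance. They were 1347 and 1356 without vehicle replicate 1, and 1190 and 967 without vehicle replicate 3. Leaving out a library of the dose itself gave 768 to 1259 at 0.01 µg/kg and 719 to 1006 at 0.03 µg/kg. DESeq2 called 15 genes at 0.01 µg/kg and 32 at 0.03 µg/kg, and at 0.01 µg/kg a fit of the 2 groups alone called 0 genes, with 740 at an unadjusted p below 0.05. At 0.03 µg/kg that fit called 3 genes, of which 1 was among the 2 called here. Without vehicle replicate 1, 2 genes were called at 0.01 µg/kg and 4 at 0.03 µg/kg, and without 0.01 µg/kg replicate 1, 2 genes were called at that dose.

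**Figure D4:**
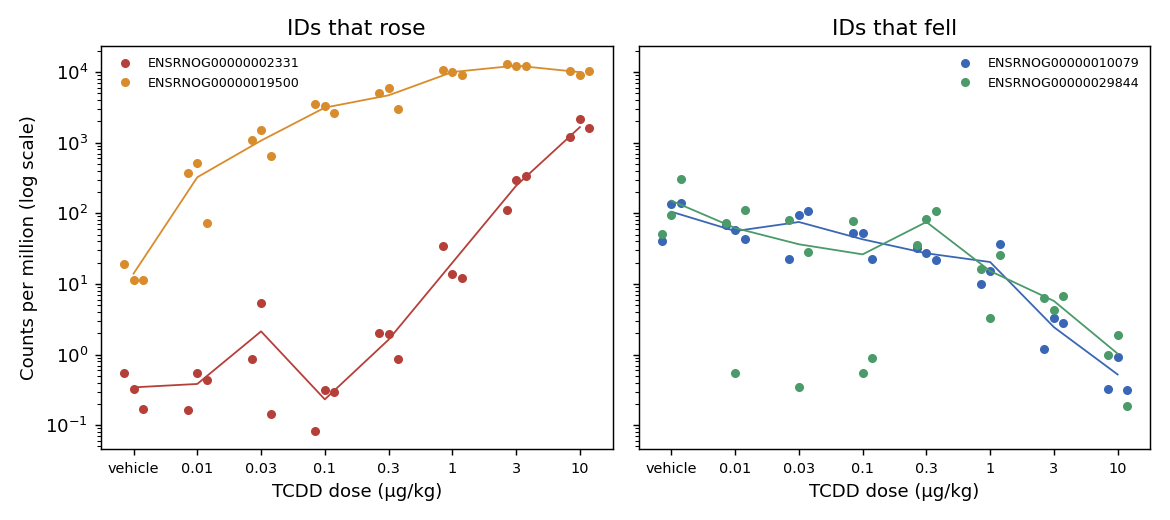
CPM in each library (vertical axis, log scale) by TCDD dose in µg/kg (horizontal axis, equally spaced groups) for the 2 named IDs that rose and the 2 that fell. Points are libraries and lines join group means. ENSRNOG00000019500 climbed from 14.0 CPM in vehicle to 12310 CPM at 3 µg/kg.

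The comparison of 10 with 3 µg/kg asks what changed between the highest doses. Here 307 genes were higher and 354 lower at 10 µg/kg, and 509 of these 661 genes had not been called at 3 µg/kg against vehicle. Of the 307 higher genes 44, and of the 354 lower genes 61, were not called at 10 µg/kg against vehicle. Of the 992 genes that rose at 3 µg/kg, 66 were higher still at 10 µg/kg and 19 were lower. Of the 665 that fell at 3 µg/kg, 57 were lower still and 10 were higher. Among the 307 higher genes, 71.7% had a log2 fold change above 0 at 1 µg/kg against vehicle (median 0.24), and 52.4% at 0.01, 63.5% at 0.03, 50.2% at 0.1 and 63.8% at 0.3 µg/kg. Among the 354 lower genes, 70.6% had a value below 0 at 1 µg/kg (median -0.16), and 42.1% at 0.01, 49.2% at 0.03, 51.4% at 0.1 and 54.5% at 0.3 µg/kg. These shares were not tested. The count of 661 was 414, 340 and 430 without 3 µg/kg replicates 1, 2 and 3, 239 and 202 without 10 µg/kg replicates 2 and 3, and 279 in a fit of the 2 groups alone.

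Most genes called at a lower dose were called again at 10 µg/kg in the same direction. Of 1716 genes called at 1 or more doses below 10 µg/kg, 1326 were called at 10 µg/kg with the same sign, 3 with the opposite sign and 387 were not called. Another 2201 genes were called at 10 µg/kg alone. A call at that dose alone does not show a difference from the lower doses. The genes called for 10 against 3 µg/kg were not counted among them. Doses of 3 and 10 µg/kg shared 813 rises and 490 falls, where independent lists would share 146 and 90.1, and the simulations of unchanged groups shared 0. That 0 is no reference for the size of the overlap, since unchanged groups gave at most 1 call in any simulated comparison. Across genes, which are not independent replicates, the covariance of the log2 fold changes at 3 and 10 µg/kg was 0.643 against 0.0643 in the simulations, and r was 0.799 against 0.513. At 0.1 µg/kg the covariance with 10 µg/kg was 0.233 against 0.0637, and at 0.01 µg/kg 0.131 against 0.0645. The simulated genes varied independently around a mean over all groups, so they may understate what noise in the vehicle libraries adds. The excess in covariance is therefore no measure of a shared dose effect. The correlation across genes with 10 µg/kg lay below that of the simulations at the lowest 3 doses. It was 0.284 against 0.511 at 0.01 µg/kg, 0.366 against 0.517 at 0.03 µg/kg and 0.447 against 0.508 at 0.1 µg/kg. The simulated r is no reference for r at any dose. Simulated groups held no dose effect, while in the data genes changed at 10 µg/kg alone can lower r. Part of each overlap beyond independent lists, and of each covariance beyond the simulations, may come from the shared vehicle libraries.

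Across all groups, 2625 genes differed among doses by the F test. The trend on dose rank called 4196 genes, 2224 with a rising and 1972 with a falling slope. No omission of any 1 of the 24 libraries and no other setting tried moved these counts by more than 1.5 times.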

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

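The tests of not-unique alignments and of the replicate number were chosen only after the result was seen; the tests of scaling, of the vehicle libraries, of depth along the axis within groups and of reads outside genes were set beforehand.

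The share of alignments that were not unique, which the comparisons do not use, averaged 32.0% ± 2.85 (SD, n = 3) at 10 µg/kg and 24.1% ± 0.797 (SD, n = 3) in vehicle, a signal above the control samples in data outside the main measurement. The 3 libraries at 10 µg/kg held 29.3% to 35.0% and the other 21 libraries 21.0% to 25.8% (exact two-sided permutation p = 0.000494 over 2024 arrangements). Against the 3 vehicle libraries alone the exact permutation p was 0.10, the smallest that 3 against 3 allows. Depth in gene counts is argued against, since the highest share among the 4 other libraries at least as deep as the shallowest at 10 µg/kg was 24.5%. Depth in all alignments could not be tested this way, since that total includes the not-unique alignments themselves. By that total the deepest other library held 25500791 (22.1% not unique), and the shallowest at 10 µg/kg 25677684 (29.3%). Their gene counts were 15760143 and 14832271. Genes already at their 10 µg/kg level at 3 µg/kg are argued against only for the net share. Its mean at 3 µg/kg differed from vehicle by -1.97 points, but falls of other transcripts there could have hidden such a rise. Transcripts changing between 3 and 10 µg/kg, untested here, and a library batch stay open, as does depth in all alignments. The labels name a batch for 0 of the 24 libraries and number the rats in order of dose, so a batch and the dose cannot be told apart.

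Calls at 0.1 µg/kg were mostly rises, 109 of 115 genes (94.8%), while at an unadjusted p below 0.05 the balance was 1031 rises to 605 falls. Scaling of the libraries stays open: 94.7% of calls rose under RLE scaling, but this scaling left the median log2 fold change of all genes nearly where it was (-0.0231 against -0.0226), so that it could hardly have moved the share. A single vehicle library stays open: the share of rises was lowest, at 79.5% of 44 calls, without vehicle replicate 1. That was just under the bound of 80 set for this test. All 9 calls left without vehicle replicate 2 were rises, as were 97.3% of 147 without vehicle replicate 3. The dose itself is a further open explanation, since 93 of the 109 rises were called again at 10 µg/kg in the same direction, with the same vehicle libraries.

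Differences among libraries within groups shared an axis that held 22.4% of the variance around the group means. The 8 libraries numbered 3 had a mean of 17.4 ± 9.15 (SD) and were all above 0, against -4.79 ± 14.5 for number 2 and -12.7 ± 15.8 for number 1 (permutation p = 0.011 within groups, 100000 resamples). This is consistent with a factor that follows the replicate number, which the labels do not describe. Depth had r = -0.10 (permutation p = 0.653) and rho = -0.205 (permutation p = 0.357). The share of reads outside genes had r = 0.031 (permutation p = 0.918) and rho = 0.179 (permutation p = 0.489). By the bound set beforehand, r this small would have argued against both explanations. Both stay open, as the 95% intervals of r, added after r was seen, were too wide to decide, at -0.554 to 0.40 and -0.456 to 0.504. Without the 2 libraries farthest from the median, r was -0.179 and 0.361; over these 2 relations the Benjamini-Hochberg adjusted p was 0.918 for both, and no biological explanation was tested.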

How the results depend on the processing

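RLE scaling and both other low-count filters left every count within 1.5 times of its value. DESeq2 called 625, 524, 313, 32 and 15 genes at 1, 0.3, 0.1, 0.03 and 0.01 µg/kg, where edgeR called 264, 258, 115, 2 and 1; at 0.03 µg/kg 16 of its calls were rises and 16 falls. A fit of the 2 groups alone, with fewer libraries to estimate the spread, called 0, 42, 7, 54 and 757 genes at 0.01, 0.1, 0.3, 1 and 3 µg/kg, 3 at 0.03 µg/kg (1 of them among the 2 genes called with all groups), and 279 for 10 against 3 µg/kg. In that fit ENSRNOG00000019500 at 0.01 µg/kg kept a log2 fold change of 4.52 but had an edgeR adjusted p of 0.502. Over its alternatives the adjusted p ran from 1.95e-22 (DESeq2) to 0.502 (that edgeR fit). The other 59 of 60 values kept direction and call. The 60 values cover the 4 named IDs at 10 µg/kg and ENSRNOG00000019500 at 0.01 µg/kg, and their calls at other doses were not tried. Leaving out each library of the 2 groups compared in turn, or each of all 24 for any dose and the trend, gave 1 to 2 genes at 0.01 µg/kg, 2 to 4 at 0.03, 9 to 147 at 0.1, 15 to 465 at 0.3, 66 to 543 at 1, 812 to 1474 at 3, 2618 to 3393 at 10, 202 to 753 for 10 against 3, 1813 to 2923 for any dose and 3550 to 4348 for the trend. Some counts rose when a library was left out, and the cause was not tested. With the replicate number as a block, 183 genes were called at 0.1 µg/kg, 3773 at 10 µg/kg and 934 for 10 against 3 µg/kg. The labels do not say that a number marks a shared factor, and 42 of 84 same-number pairs correlated above 0.1 (median 0.098), so the numbers were not taken to pair the samples. As a hint from the data, 41 of 168 different-number pairs did (median -0.057), and 15 of 24 libraries correlated best with their own number. Number 3 stood out, with 18 of 28 pairs above 0.1 (median 0.171). The gene list tests could not be run. With 3 libraries per group at these depths, 54 of 100 simulated 2-fold changes were found for 10 µg/kg against vehicle. That simulation changed 200 of 12496 genes, while 3530 were called in the data, so the share found does not carry over to the data.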

Other observations

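The splits below were planned; the other values were chosen only after the data were seen. Of the 1837 genes that rose at 10 µg/kg, 813 (44.3%) had also been called at 3 µg/kg, and 187 (10.2%) were called without a break from 1 µg/kg or lower up to 10 µg/kg. Of the 1693 that fell, the counts were 490 (28.9%) and 42 (2.48%). A difference between rises and falls was not tested, since genes are not independent replicates.

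The calls at 0.1 µg/kg shared 43 genes with the 264 called at 1 µg/kg and 86 with the 258 called at 0.3 µg/kg, in the same direction and against the same vehicle libraries. Independent lists would share 1.85 rises and 0.025 falls at 1 µg/kg, and 2.09 rises and 0.009 falls at 0.3 µg/kg. The simulations of unchanged groups shared 0 calls for both pairs of doses, which is no reference, since they gave at most 1 call in any comparison. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.185 between 0.1 and 1 µg/kg, against 0.0622 in the simulations, and 0.205 between 0.1 and 0.3 µg/kg, against 0.0639. The part of either overlap or covariance that comes from the shared vehicle libraries was not separated, and a difference between the overlaps was not tested. At 1 µg/kg, replicate 1 lay at -2.39 on the first principal component, where the group reached 17.4, and 543 genes were called without it.

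ENSRNOG00000029844 had 7, 5, 7 and 12 counts in 4 libraries of the 0.01, 0.03 and 0.1 µg/kg groups, while the other 5 libraries of these groups held 391 to 1530 counts.

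The number of IDs detected, not tested, was 14568 ± 53.5 in vehicle and 15270 ± 114 at 10 µg/kg (SD, n = 3).

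Other splits of the same libraries into groups of equal size were refitted. For any dose, 1 of 100 splits, the real split, gave 2625 genes and the highest other gave 292. Chance is thus argued against, although this number of splits cannot exclude it. For the dose trend it was likewise 1 of 100, with 4196 genes in the real split and 449 in the highest other. A pair of groups of 3 libraries allows 10 splits, which are too few for a share under 0.05. For 10 µg/kg against vehicle 1 of the 10 splits gave as many genes, with 3530 in the real split and 0 in the highest other, and the values were 1657 and 2 at 3 µg/kg, 264 and 89 at 1 µg/kg, 258 and 1 at 0.3 µg/kg, 115 and 0 at 0.1 µg/kg, 2 and 0 at 0.03 µg/kg, and 661 and 0 for 10 against 3 µg/kg, again 1 of 10 splits each. For 0.01 µg/kg against vehicle 3 of the 10 splits gave as many as the real 1 gene, and the highest other gave 3.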
